A study of Homo sapiens with 6 samples.

How the data were processed

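RNA of 6 cultures of MCF-7 cells was hybridised to single-colour oligonucleotide arrays after biotin labelling, 3 cultures in 25 mM glucose and 3 in 10 mM fructose. Per the labels' protocols, cells had spent 25 days in the sugar with regular passage, and RNA was taken at about 70% confluency, about 24 hours after fresh medium. Per the series' design text the replicates were separately adapted batches of cells, so the spread between arrays includes that between batches. Groups and replicate numbers came from the sample titles.

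The deposited values are intensities summarised per probe set with RMA, per the submitters' processing notes; its software, version and settings are not given in the sources used here. RMA corrects background, equalises the distributions of the arrays and fits 1 value per probe set, so differences shared by all genes of an array are removed before deposit. The deposited intensity was on a linear scale, from 1.74 to 10228, with no missing value and none below 0, and was turned to log2 with no pseudocount. The test had been planned for log2 values and was run on these. Array medians on the log2 scale differed by at most 0.0618. No array measure of signal over background was used, so values near the bottom of the range understate changes.

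Probe sets were named through the platform annotation supplied with the series. Of 32321 probe sets, 19158 had 1 gene symbol, 1388 had several and 11775 had none there. Those with 1 symbol were used, and 19128 of them matched the RefSeq gene table of assembly GRCh38 by Entrez identifier, with 0 symbols changed and 30 unmatched. The table gave names, gene types, lengths and the order of genes; the build behind the array design is not given in the sources used here, so no coordinates are printed. Where a gene had several probe sets (637 genes), the one with the highest mean over the 6 arrays stood for it, which left 18404 genes. Controls for RNA quality by position along the transcript were planned and could not be run, because 0 rows carried names of control probe sets.

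Each gene was tested with limma (lmFit and eBayes, two-sided) as fructose against glucose, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Fold changes are fructose minus glucose on the log2 scale, and "rose" or "fell" is used only of genes past the threshold. Gene lists were tested with limma's camera, which compares a list with all other genes, at a preset correlation between genes of 0.01 and with adjustment over 36 lists. Another list, of transcripts encoded by mitochondrial DNA, had 0 measured members and was not tested. The 37 lists held 856 entries, of which 756 were measured; the others, among them HMGCR, LDLR, G6PD, ALDOB and SORD, were not analysed here. Estimated correlations and fry, which asks whether a list's genes move on balance 1 way, were alternatives. Counts "adjusted over the list alone" use Benjamini-Hochberg within the list. In 8 lists, none of them called, the median, the mean and the direction from camera differed in sign.

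The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule took the 12 largest rises and 12 largest falls among called genes whose arrays did not overlap between sugars, and up to 2 risers and 2 fallers of each list, or the 2 smallest p where none passed. It also named TXNIP, ARRDC4, SLC2A1, SLC2A5, KHK, HK2, LDHA, CTBP1, CTBP2, ESR1 and BRCA1 whatever their values. Alternatives fixed at the same time were the replicate number as a block, each array left out in turn, a filter on dim probe sets (below the 40th percentile of mean intensity), averaged probe sets, quantile normalization, median centring, array weights, a trended and robust prior, every probe set tested on its own, an ordinary linear model and a threshold of 0.01. Protein-coding genes only and the removal of chromosome stretches were chosen after seeing the data, as was the analysis of neighbouring genes. The removed genes were themselves picked by their fold changes, so that alternative lowers counts by construction.

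For that analysis, genes with a mean log2 intensity of at least 5 were placed in order, 9661 in all, and the median fold change of each window of 51 was set against 1000 shuffles of the order. On simulated data with the spread of these arrays, the gene test recovered 99.0% of 100 genes changed by 1 on the log2 scale and 76.0% of 100 changed by 0.5 among 18404 genes. Of 193 calls 15 were false, and 3 were members of a planted list of 20 genes shifted by 0.3. Work was done in R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.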

Results

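Gene expression was measured in MCF-7 cells, an estrogen receptor-positive human breast cancer line of luminal type. The cells had grown for 25 days in DMEM that held glucose (25 mM) or, in its place, fructose (10 mM), a sugar that many cultured cells break down by glycolysis more slowly than glucose. Each sugar was represented by 3 arrays, and the series' design text describes the replicates as batches of cells adapted separately. The title of the series names the question as the effect of restricted glycolysis on gene expression. The table held 32321 probe sets, of which 18404 genes with a single symbol were tested. The number of arrays limits the precision. Pairs of arrays correlated at 0.990 to 0.993 within a sugar and at 0.988 to 0.990 between sugars, and the first principal component, with 46.1% of the variance, separated the sugars.

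The largest change was in TXNIP, an arrestin that restrains glucose uptake and is induced by glucose. Its log2 intensity was 9.36 ± 0.09 (SD, n = 3) in glucose and 4.55 ± 0.21 (SD, n = 3) in fructose, a 27.9-fold fall (adjusted p = 7.91e-07). Across all genes, 958 differed between the sugars at an adjusted p under 0.05, with 598 higher and 360 lower in fructose. Of these, 77 changed by at least 1 on the log2 scale, 57 upward and 20 downward. The arrays of the sugars did not overlap in 26.7% of genes, against 10% for chance splits of 3 against 3.

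**Figure D1:**
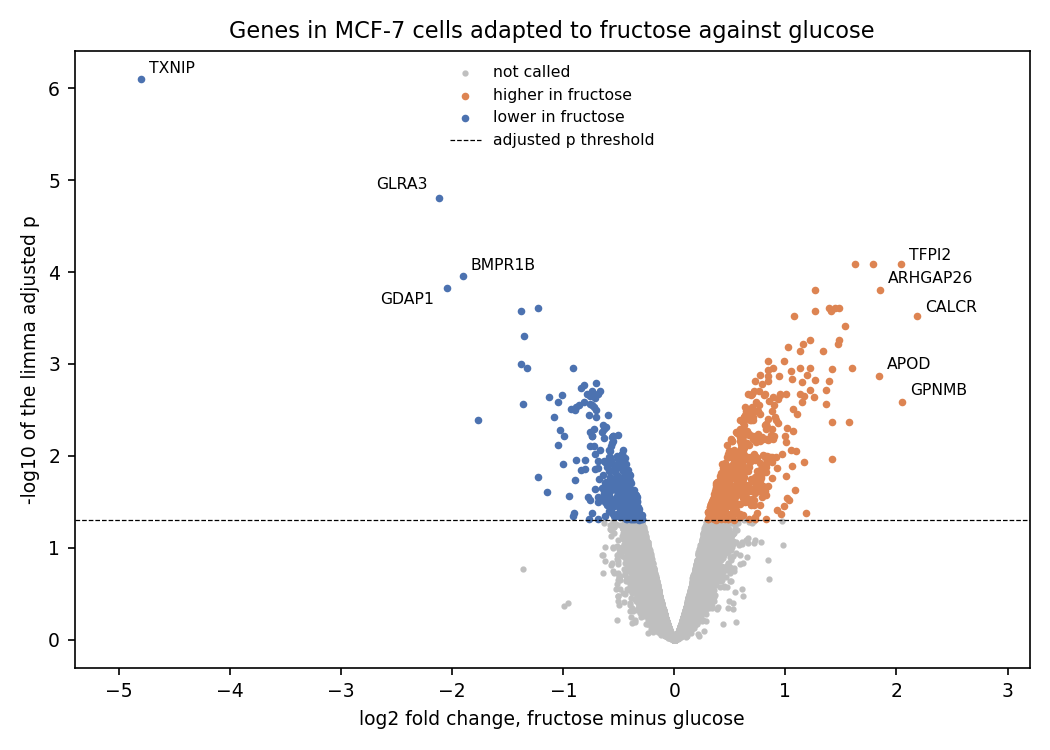
Each point is 1 of 18404 genes, with its log2 fold change (fructose minus glucose) on the horizontal axis and the negative log10 of its limma adjusted p on the vertical axis. Colours mark the 598 genes higher and the 360 lower in fructose, and TXNIP stands apart at a log2 fold change of -4.80.

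Among the genes with the largest rises were CALCR, the calcitonin receptor, and TFPI2, a secreted inhibitor of serine proteases. CALCR went from 3.63 ± 0.32 to 5.82 ± 0.11 (SD, n = 3 each), a log2 fold change of 2.19 (SE 0.15, adjusted p = 0.000299). TFPI2 rose by 2.04 (SE 0.10) and GPNMB, a transmembrane glycoprotein of lysosomes, by 2.05 (SE 0.22). The Rho GTPase-activating protein ARHGAP26 rose by 1.85 and the lipocalin APOD by 1.84. AKR1C2 and AKR1C1, aldo-keto reductases that act on steroids, rose by 1.79 and 1.62. Those paralogs have nearly identical sequences, so the values of each are uncertain on their own. ANXA3, ZNF208, S100A14, the actin-bundling protein PLS3 and the nuclear receptor PPARG completed the 12 largest rises, with log2 fold changes between 1.48 and 1.60. ZNF208 stayed dim, at 1.72 in glucose and 3.29 in fructose, near the bottom of the intensity range. CALCR and GPNMB were dim in glucose too, at 3.63 and 3.49, below the medians of the glucose arrays (4.60 to 4.64). The sizes of their rises are therefore less certain.

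After TXNIP, the largest falls were in GLRA3, a glycine receptor subunit, and GDAP1, a protein of the mitochondrial outer membrane. GLRA3 went from 7.87 ± 0.07 to 5.75 ± 0.08 (SD, n = 3 each), a log2 fold change of -2.12 (SE 0.08, adjusted p = 1.56e-05). GDAP1 fell by 2.05 (SE 0.12) and the bone morphogenetic protein receptor BMPR1B by 1.91 (SE 0.10). TARP fell by 1.77, the tyrosine kinase FRK by 1.38, the desmosomal cadherin DSC2 by 1.38 and the noncoding RNA LINC00052 by 1.37. JPH1, CRISPLD1, TFPI and the netrin receptor UNC5C fell by 1.36, 1.32, 1.23 and 1.23. GDAP1, JPH1 and CRISPLD1 share chromosome 8, and GLRA3, BMPR1B and UNC5C share chromosome 4. These falls may therefore not all be independent of each other. Of these 24 genes, 23 stayed past the threshold under every alternative setting in which named genes were followed gene by gene. The exception was TFPI, whose adjusted p was 0.0752 without glucose array 1, 0.0570 without glucose array 3 and 0.0647 without fructose array 1. The ordinary test without moderation, where named genes were not followed, called 22 genes that changed by at least 1. It therefore cannot have called all 24.

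**Figure D2:**
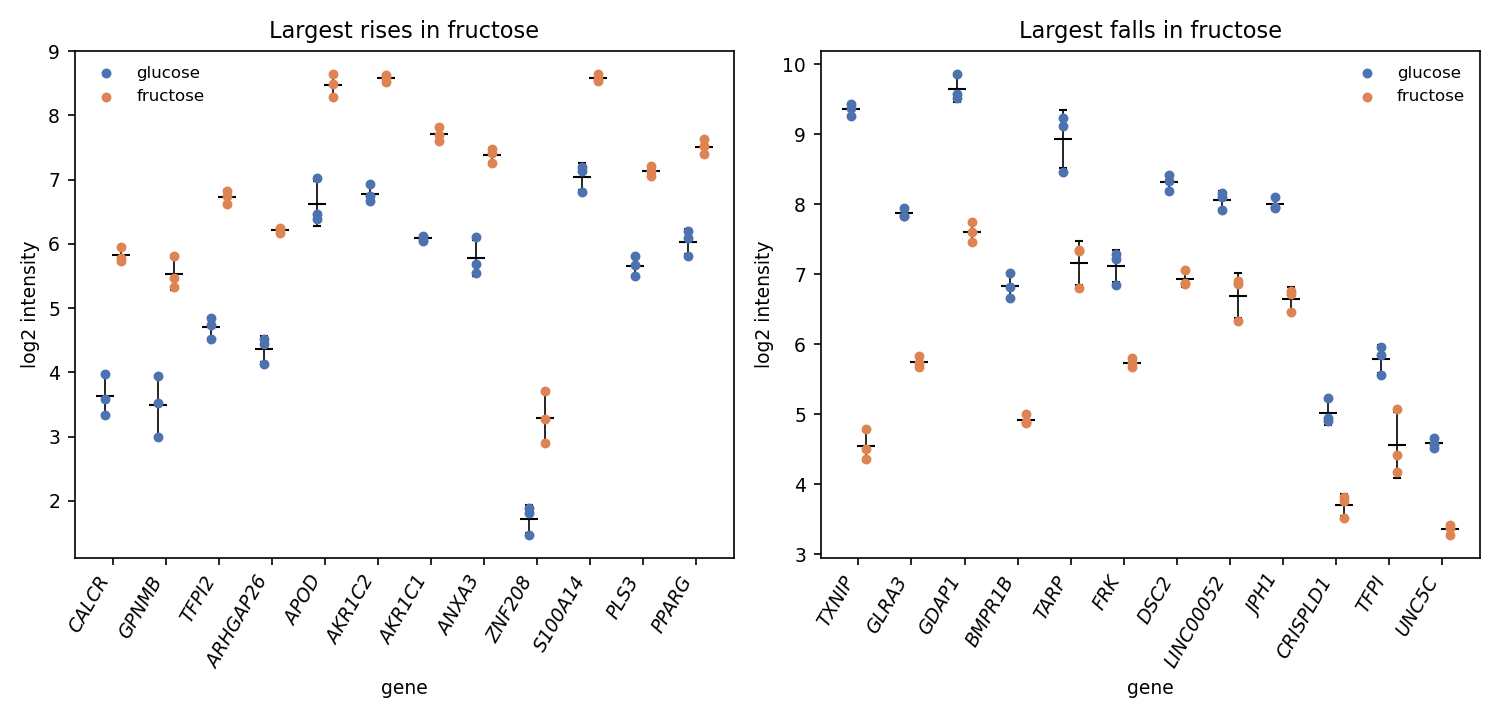
Points give the log2 intensity of the 12 genes with the largest rises and the 12 with the largest falls on each of the 3 glucose and 3 fructose arrays, and black marks with bars give the mean and SD of each sugar. For every gene shown, the arrays of one sugar lie on one side of those of the other, as the rule for naming these genes required.

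TXNIP belongs to the targets of MondoA and ChREBP, transcription factors that respond to sugar phosphates. Of the 9 measured members of that list, 3 fell and none rose over all genes (3 fell and 1 rose when adjusted over the list alone). ARRDC4, an arrestin related to TXNIP, fell from 5.71 ± 0.20 to 4.66 ± 0.27 (SD, n = 3 each), by 1.04 on the log2 scale (adjusted p = 0.00758). The other called member, RGS16, fell by 0.62 and was named after its values were seen. The list was called lower in fructose by camera (adjusted p = 0.0377; adjusted p = 0.638 with an estimated correlation), and its median log2 fold change was -0.10. That call was lost without glucose array 1 (adjusted p = 0.0906), glucose array 2 (0.0546) or fructose array 3 (0.0698), and was 0.0511 with array weights and 0.0641 without the chromosome stretches described below, 1 of which holds RGS16. Over all alternatives its adjusted p ranged from 0.00212 to 0.638. The mean of the list, -0.71, lay well below its median, and TXNIP alone was at -4.80. The list was not tested without TXNIP.

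Glycolytic enzymes as a group did not pass the test. Of 20 measured members, 1 rose and 1 fell (2 and 1 when adjusted over the list alone), with a camera adjusted p of 0.708. The riser was PFKFB2, which makes the activator of phosphofructokinase, at a log2 fold change of 0.58 (SE 0.10), and the lactate dehydrogenase subunit LDHB fell by 1.04 (SE 0.11, adjusted p = 0.00258). LDHA differed by -0.20 (SE 0.07, adjusted p = 0.173), the hexokinase HK2 by 0.24 (SE 0.08, adjusted p = 0.145) and the glucose transporter SLC2A1 by 0.16 (SE 0.08, adjusted p = 0.315). None of those 3 passed the threshold. The fructose transporter SLC2A5 was dim in both sugars, at 4.01 and 3.97, and differed by -0.04 (SE 0.08, adjusted p = 0.857). Ketohexokinase, KHK, which phosphorylates fructose, differed by -0.10 (SE 0.11, adjusted p = 0.671). In the list of fructose and polyol metabolism, 0 of 6 members passed over all genes or when adjusted over the list alone (camera adjusted p = 0.720), and the smallest p belonged to SLC2A8 (0.29) and GLYCTK (0.16).

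Enzymes of the hexosamine pathway and of N-glycan precursor synthesis were called lower in fructose by camera (adjusted p = 0.0395; adjusted p = 0.807 with an estimated correlation). Of 26 members, 1 fell and 1 rose over all genes (3 and 2 when adjusted over the list alone), and the median was -0.12. OGA, which removes O-linked N-acetylglucosamine, fell by 0.50, and the N-acetylglucosamine kinase NAGK rose by 0.32. The list's call was lost without glucose array 1 (adjusted p = 0.0906), glucose array 3 (0.117), fructose array 1 (0.0553) or fructose array 3 (0.152), and was 0.0560 with median centring, 0.0644 with fry and 0.0510 without the chromosome stretches described below. The call of NAGK was lost without any 1 of the 6 arrays (adjusted p from 0.0855 to 0.153). That of OGA was lost without any array but glucose array 2 (up to 0.0835). In the pentose phosphate pathway 0 of 10 members passed over all genes or over the list alone (camera adjusted p = 0.720), with TKT at -0.24 and PGLS at 0.31. Gluconeogenesis and anaplerosis from glutamine likewise had 0 of 16 by either adjustment (camera adjusted p = 0.605), with ME2 at -0.36 and GOT1 at 0.22.

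Cholesterol synthesis gave the smallest p of the 36 lists tested. All 18 measured members had a positive log2 fold change, with a median of 0.32, and 7 rose while 0 fell over all genes (13 and 0 when adjusted over the list alone). Camera called the list higher in fructose (adjusted p = 5.04e-10; adjusted p = 0.110 with an estimated correlation). MVD, the mevalonate diphosphate decarboxylase, rose by 0.73 (SE 0.07, adjusted p = 0.00152) and HMGCS1, the synthase that makes hydroxymethylglutaryl-CoA, by 0.65 (SE 0.10, adjusted p = 0.0102). The sterol enzymes NSDHL and EBP, named after their values were seen, rose by 0.64 and 0.37 and lie on chromosome X, which was higher as a whole. Without the chromosome stretches described below, the list's adjusted p was 1.20e-07. Fatty acid synthesis and desaturation had 1 member higher and 1 lower of 16 (1 and 2 when adjusted over the list alone; camera adjusted p = 0.720). ACSS2, which makes acetyl-CoA from acetate, rose by 0.78, and the acetyl-CoA carboxylase ACACB fell by 0.71. In fatty acid oxidation and PPAR targets 3 of 24 members fell and 0 rose (4 and 1 when adjusted over the list alone; camera adjusted p = 0.481, but fry adjusted p = 0.0413). The lipid droplet protein PLIN2 fell by 0.99 (SE 0.13) and ECI2 by 0.40. Leaving out single arrays ended the calls of ACSS2 without glucose array 1, fructose array 1 or fructose array 2 (adjusted p up to 0.0574). It ended those of ACACB without any array but glucose array 2 and fructose array 3 (up to 0.0846), and of ECI2 without any but glucose array 2 (up to 0.113).

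Estrogen receptor targets were higher in fructose by camera (adjusted p = 1.21e-07; adjusted p = 0.638 with an estimated correlation). Of 19 members 7 rose and 0 fell over all genes (12 and 0 when adjusted over the list alone), with a median of 0.25. PGR, the progesterone receptor, went from 4.83 ± 0.22 to 5.85 ± 0.17 (SD, n = 3 each), a rise of 1.02 (adjusted p = 0.00502), and the fatty acid elongase ELOVL2 rose by 0.95 (SE 0.10, adjusted p = 0.00218). The receptor gene itself, ESR1, differed by 0.15 (SE 0.09, adjusted p = 0.405). The list of luminal epithelial identity had 1 member higher and 1 lower of 19 (3 and 1 when adjusted over the list alone; camera adjusted p = 0.481). AGR2, a secreted disulfide isomerase, rose by 0.58, and the claudin CLDN7 fell by 0.34. Without single arrays, AGR2 lost its call in 4 cases, all but glucose arrays 1 and 2 (adjusted p up to 0.0782), and CLDN7 in all 6 (0.0734 to 0.121).

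FOXO targets and insulin signalling were called higher in fructose by camera (adjusted p = 0.0377; adjusted p = 0.668 with an estimated correlation), with 5 of 19 members higher and 0 lower (6 and 0 when adjusted over the list alone). The sestrin SESN3 rose by 0.88 and the repressor BCL6 by 0.54. The call of the list was lost without glucose array 1 (adjusted p = 0.136) or fructose array 1 (0.0842), without dim probe sets (0.0709), with median centring (0.0535) and with fry (0.0918). SESN3 lost its own without glucose arrays 1 or 2 or fructose array 2 (up to 0.0750), and BCL6 without any array but glucose array 2 (up to 0.132). CTBP1, which encodes a corepressor that binds NADH, rose by 0.37 (SE 0.08, adjusted p = 0.0361). It lies in a stretch of chromosome 4 that was higher as a whole, and its call was lost without any 1 of the 6 arrays (adjusted p from 0.0647 to 0.123). Its paralog CTBP2 differed by -0.08 (SE 0.08, adjusted p = 0.615).

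**Figure D3:**
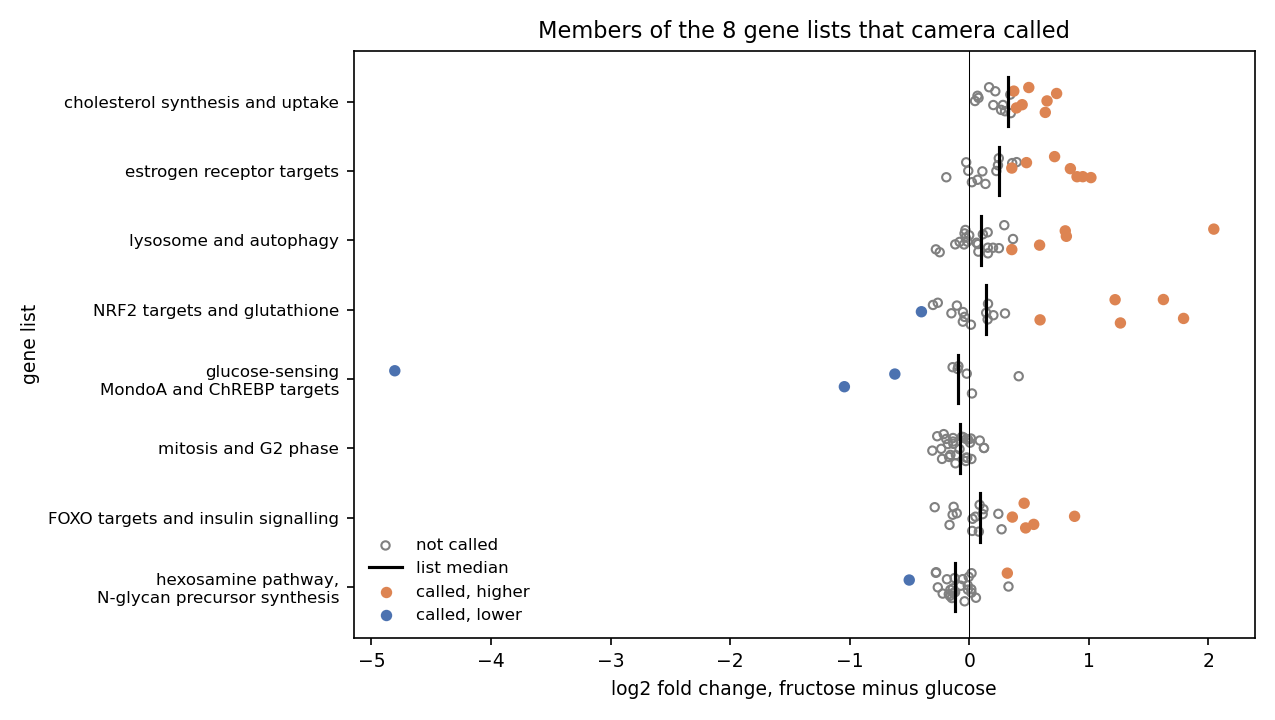
Each point is a member of 1 of the 8 lists that camera called, placed by its log2 fold change (fructose minus glucose); filled points passed the test over all genes, and black bars mark list medians. All 18 members of the cholesterol list lie above 0, and none of the 29 members of the mitosis list passed.

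Lysosomal genes were called higher in fructose by camera (adjusted p = 0.00797; adjusted p = 0.638 with an estimated correlation). Of 26 members 5 rose and 0 fell (8 and 1 when adjusted over the list alone), led by GPNMB and the sialidase NEU1, which rose by 0.81 (SE 0.12, adjusted p = 0.0102). A positive log2 fold change was seen in 16 members, and the list's median was 0.095, below its mean of 0.22. NRF2 targets and glutathione genes were called higher as well (adjusted p = 0.0195; adjusted p = 0.638 with an estimated correlation; 0.0600 without glucose array 3). There 5 of 19 members rose and 1 fell (7 and 3 when adjusted over the list alone), 11 had a positive log2 fold change, and the median was 0.14. AKR1C2 and AKR1C1 led the risers, and AKR1C3, another close paralog named after its values were seen, rose by 1.26. These paralogs are most of the risers and may share 1 signal, and the list was not tested without them. ABCC2, an efflux pump, fell by 0.40, and lost its call without any array but fructose array 3 (adjusted p up to 0.154).

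Other stress responses did not pass as groups. The amino acid response of ATF4 and CHOP had 1 member higher and 2 lower of 25 (2 and 3 when adjusted over the list alone; camera adjusted p = 0.857). NUPR1, a stress-induced chromatin protein, rose by 1.41 (SE 0.09, adjusted p = 0.000267). The amino acid transporter subunits SLC7A5 and SLC3A2 fell by 0.51 and 0.40, the latter losing its call without any array but glucose array 3 (adjusted p up to 0.0956). Endoplasmic reticulum chaperones had 0 members higher and 1 lower of 22 by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.708). The 1 was ATF6, which fell by 0.36, lies in a stretch of chromosome 1 that was lower as a whole, and lost its call without any array but glucose array 2 (up to 0.117). In the heat shock response 0 of 13 passed by either adjustment, including adjusted over the list alone (camera adjusted p = 0.117; 0.0324 without glucose array 2 and 0.0429 without fructose array 2), with HSPA4 at -0.28 and BAG3 at -0.24.

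Nuclear genes of the mitochondrion differed little. Respiratory complex I had 1 member higher of 34 and none lower (0 and 0 when adjusted over the list alone; camera adjusted p = 0.473), namely NDUFV1 at 0.32. Complexes III and IV with ATP synthase had 0 of 34 by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.857), with COX5B at 0.29 and UQCRC2 at -0.21. In pyruvate dehydrogenase and the citric acid cycle 1 of 22 rose and 0 fell (2 and 0 when adjusted over the list alone; camera adjusted p = 0.473), namely IDH3G at 0.30, on chromosome X. Both calls were lost without any 1 of the 6 arrays (adjusted p from 0.0728 to 0.140 for NDUFV1 and from 0.0861 to 0.134 for IDH3G). The mitochondrial ribosome had 0 of 45 (camera adjusted p = 0.857), with MRPL27 and MRPS11 at 0.30 each, and cytosolic ribosomal proteins 0 of 45 (camera adjusted p = 0.708), with RPL32 at -0.25 and RPL10A at 0.17. Counts adjusted over the list alone were also 0 for both ribosomes. Transcripts encoded by mitochondrial DNA were not analysed here.

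Genes of mitosis and the G2 phase were called lower in fructose by camera (adjusted p = 0.0377; adjusted p = 0.898 with an estimated correlation), although 0 of 29 members passed over all genes or when adjusted over the list alone. The median was -0.08, with NDC80 at -0.31 and KIF11 at -0.23. This call was lost without glucose array 1 (adjusted p = 0.261), glucose array 3 (0.0969) or fructose array 3 (0.176), with median centring (0.0560) and with fry (0.229). DNA replication had 0 members higher and 1 lower of 33 (0 and 2 when adjusted over the list alone; camera adjusted p = 0.0721), namely RRM1, a ribonucleotide reductase subunit, which fell by 0.34 and lost its call without any 1 of the 6 arrays (0.0635 to 0.153). That list was called without glucose array 2 (0.0439), without fructose array 2 (0.0429) or without the chromosome stretches (0.0233). Homologous recombination and crosslink repair had 0 higher and 1 lower of 19 by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.0531; 0.0241 without glucose array 2, 0.0475 without fructose array 2, 0.0436 with quantile normalization and 0.0460 with protein-coding genes only). MRE11, a nuclease subunit, fell by 0.43 (SE 0.07; adjusted p = 0.0123, and 0.0549 without fructose array 1). BRCA1 differed by -0.08 (SE 0.09, adjusted p = 0.680). Replication-dependent histones had 0 of 14 by either adjustment, including adjusted over the list alone (camera adjusted p = 0.935), with H2BC12 at 0.37 (adjusted p = 0.0842, and 0.0464 without fructose array 3) and H1-2 at 0.16. Of 23 p53 targets 1 rose and 1 fell (1 and 2 when adjusted over the list alone; camera adjusted p = 0.708). TIGAR rose by 0.38 and DDB2 fell by 0.38, and both lost their calls without any 1 of the 6 arrays (0.0564 to 0.113 and 0.0572 to 0.122).

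Markers of other cell types did not move as groups. The mesenchymal and fibroblast list had 2 members higher and 1 lower of 19 (2 and 2 when adjusted over the list alone; camera adjusted p = 0.891). The repressor SNAI2 rose by 1.13 (SE 0.09, adjusted p = 0.000729) and fibronectin, FN1, by 0.70 (SE 0.07), while the collagen COL3A1 fell by 0.43 and lost its call without any array but glucose array 3 (up to 0.10). Basal and squamous markers had 1 higher and 1 lower of 8 (1 and 2 when adjusted over the list alone; camera adjusted p = 0.841), TRIM29 at 0.59 and CDH3 at -0.36, neither called without any 1 of the 6 arrays (adjusted p up to 0.113 and 0.0996). Leukocyte and endothelial markers had 1 higher and 0 lower of 13 by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.481). That 1 was LCP1, an actin-bundling protein of blood cells also found in carcinoma lines, which rose by 1.39 (SE 0.09, adjusted p = 0.000249).

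Neighbouring genes along the chromosomes moved together. In windows of 51 genes in genomic order, the largest absolute median log2 fold change was 0.27, against 0.13 for the 95th percentile of the largest windows in 1000 shuffled orders. Windows past that value formed 9 stretches on 7 chromosomes, 5 higher and 4 lower in fructose. Chromosome X was higher from PLCXD1 to VAMP7, a stretch that held all of its 276 placed genes, with a median of 0.18, and 53 of them rose and 2 fell. On chromosome 7, the stretch from TMEM60 to NDUFA5 had a median of 0.17, and 22 of its 124 genes rose while 1 fell. On chromosome 4, the stretch from ZNF718 to TMEM165 had a median of 0.15, with 11 of 117 higher and 0 lower. Chromosome 1 was lower from UFC1 to LAD1 (median -0.13, with 3 of 100 genes higher and 14 lower) and higher from NSL1 to ZNF692 (median 0.14, with 14 of 105 higher and 1 lower). CALCR and TFPI2 lie in the stretch of chromosome 7, CTBP1 in that of chromosome 4, PLS3 and IDH3G on chromosome X, and RGS16 and ATF6 in the lower stretch of chromosome 1. The strongly lower genes GDAP1, JPH1 and CRISPLD1 of chromosome 8 and GLRA3, BMPR1B and UNC5C of chromosome 4 lie outside the stretches. Runs of neighbours much shorter than 51 genes were not tested, so a shared local change of these genes stays open. The stretches held 11.4% of the genes tested and 19.3% of those called, 185 of 958, an excess that follows in part from their choice by fold change.

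**Figure D4:**
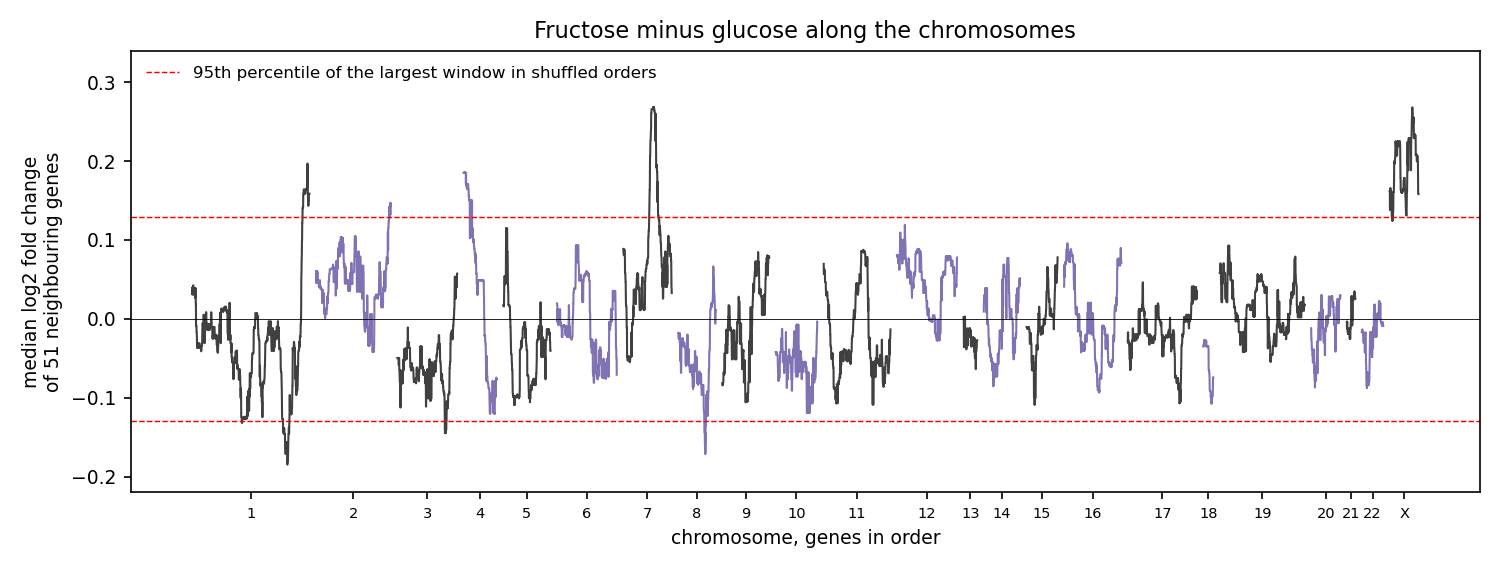
The line gives the median log2 fold change (fructose minus glucose) of 51 neighbouring genes in genomic order, chromosome by chromosome, and dashed lines mark the 95th percentile of the largest window in shuffled orders, 0.13 in either direction. Nearly all of chromosome X and parts of chromosomes 1, 2, 4 and 7 rise above it, and parts of chromosomes 1, 3 and 8 fall below it.

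In all, 8 of 36 lists were called by camera, 5 higher and 3 lower, and 0 with an estimated correlation. Leaving out 1 array lowered the 958 called genes to 617 without glucose array 2, 530 without glucose array 3, 450 without fructose array 3, 413 without glucose array 1, 378 without fructose array 2 and 371 without fructose array 1. An ordinary linear model without moderation called 95 genes, and a trended and robust prior called 1899.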

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

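Which probe sets differ outside the named genes was looked at after the main comparison, with every probe set tested on its own by limma. Of 11775 probe sets without a gene name in the annotation used here, 56 differed between the sugars, 21 higher and 35 lower in fructose. They were flagged because they carry a signal in data that the gene comparison left out. The annotation used here does not say what they detect, so control probe sets of the array may be among them. The largest of them, probe set 8175531, went from 2.73 ± 0.26 to 5.65 ± 0.26 (SD, n = 3 each), a log2 fold change of 2.92 (SE 0.18, adjusted p = 0.00480), which is above the largest rise of any named gene. Probe set 7893358 went the other way, from 4.75 ± 0.26 to 2.29 ± 0.60, a log2 fold change of -2.47 (adjusted p = 0.0262). Of 1388 probe sets with several gene symbols, 17 differed, 11 higher and 6 lower, and they were flagged for the same reason. Single values that lie apart from their group were not searched for in groups of 3 arrays.

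Of the 10 ways to split the 6 arrays into 3 and 3, only 1, the real one, called as many genes. It called 958 and the highest of the others called 0. With 10 splits the share cannot fall under 0.05.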

How the results depend on the processing

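Removing chromosome stretches and keeping protein-coding genes were chosen after seeing the data; the rest was planned. The cause of each shift was not tested. Against 958 called genes (598 higher, 360 lower) and 8 lists, the replicate block gave 560 (375 and 185) and 4 lists; 520 of the 560 were among the 958. The lists no longer called with the block were MondoA and ChREBP targets, FOXO targets, hexosamine and mitosis (adjusted p = 0.0572 each). Arrays with the same number did not deviate together (residual correlations 0.07, -0.02 and 0.02), and 3 of 6 correlated best with their own number. Without 1 array, 371 to 617 genes were called, 247 to 389 higher and 123 to 250 lower, with 4 to 11 lists. Without dim probe sets 1352 were called (798 higher and 554 lower). Median centring called 1017 (729 and 288) and 5 lists, and a trended and robust prior called 1899 (1043 and 856). Genes changed between fructose and glucose (genes higher in fructose, genes lower in fructose) numbered 326 (207, 119) with every probe set on its own, 95 (60, 35; 22 of at least 1) with the ordinary test without moderation and 232 (166, 66) at adjusted p threshold 0.01. With an estimated correlation 0 lists were called; fry called 6 on direction and 34 for change either way. Without the stretches 727 genes were called (436 and 291) and 7 lists. No result changed direction past the threshold. Of 69 called named genes 40 stayed called in all settings that tested them and were followed gene by gene. The call was lost without some array by 29 and without any 1 of the 6 by 10, and 15 uncalled ones were called somewhere. Named genes were not followed with every probe set on its own, the ordinary test or the threshold of 0.01. The block ended the calls of 19 named genes (ABCC2, ATF6, BCL6, CDH3, CLDN7, COL3A1, CTBP1, DDB2, ECI2, IDH3G, IER3, NAGK, NDUFV1, NFKBIA, OGA, RRM1, SLC3A2, TIGAR and TRIM29), and leaving out the stretches that of ABCC2. Quantile normalization ended the calls of ABCC2, KLF6 and RRM1, and median centring those of ATF6, CLDN7 and RRM1. Cholesterol, estrogen receptor and lysosome lists lost their calls only with an estimated correlation. The planned control for RNA quality was not run.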

Other observations

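Several lists outside the metabolic and hormonal ones held single genes that changed. In the hypoxia response without glycolytic enzymes, 1 of 21 members rose and 2 fell (2 and 3 when adjusted over the list alone; camera adjusted p = 0.708). EGLN3, a prolyl hydroxylase, rose by 0.60 (SE 0.09, adjusted p = 0.00828). The collagen-modifying enzymes PLOD2 and P4HA1 fell by 0.49 and 0.48; PLOD2 lies in a lower stretch of chromosome 3 and was not called without fructose array 1 (adjusted p = 0.0569), nor P4HA1 without fructose array 2 (0.0607). Of 19 genes of NF-kappa-B and cytokines, 2 rose and 0 fell (3 and 2 when adjusted over the list alone; camera adjusted p = 0.553). These were NFKB1 at 0.47 (SE 0.07, adjusted p = 0.0102) and its inhibitor NFKBIA at 0.41, the latter not called without any array but glucose array 3 (up to 0.0785). The interferon response had 0 higher and 1 lower of 30 by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.708). That 1 was IFIH1, an RNA sensor, which fell by 0.51 and was not called without glucose arrays 1 or 3 or fructose arrays 2 or 3 (up to 0.0775).

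Immediate early genes had 1 member higher and 1 lower of 22 (3 and 3 when adjusted over the list alone; camera adjusted p = 0.857), KLF6 at 0.48 and IER3 at -0.52. KLF6 was not called without any array but glucose array 2 (adjusted p up to 0.142), nor IER3 without any but glucose array 2 and fructose array 2 (up to 0.0972). In serine and one-carbon metabolism 1 of 12 rose and 0 fell by either adjustment, including adjusted over the list alone (camera adjusted p = 0.816), namely the amino acid transporter SLC1A4 at 0.75 (SE 0.11, adjusted p = 0.0104). Metallothioneins had 0 of 7 over all genes and 2 lower when adjusted over the list alone (camera adjusted p = 0.315), with MT2A at -0.30 and MT1X at -0.27.

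Every test below was added once its pattern had been seen. Chosen after the result was seen were the tests of RNA length, other short RNAs, host genes, genes between those used to find stretches, called genes kept in place and the separation of arrays, the removal of the stretches, and the way windows were merged into stretches. Small nucleolar RNA genes were lower in fructose: 0 of 175 rose and 18 fell, against 342 of 18229 other genes (Fisher's exact test, two-sided, p = 1.06e-08, across genes). That p treats genes as independent, while several of the 18 share a host gene (5 in GAS5, 3 in RABGGTB and 2 in SNHG1). It does not measure the spread between cultures. A lower recovery of all short RNAs did not meet its prediction. Other short RNAs with a mean log2 intensity of at least 4 had a median of -0.0436 over 57 genes. The median of 102 small nucleolar RNAs past the same cut was -0.22 (permutation p = 4e-04 for the difference). The groups were not matched on brightness, and the others included microRNA genes, a class with a median log2 intensity of 2.78. Dim genes can understate a change, so the test cannot exclude a lower recovery of all short RNAs. Lower host genes are argued against for 4 of the 18, whose hosts each had a 95% interval above that of the small nucleolar RNA, but stay open for 3 inside RABGGTB (-0.3109, adjusted p = 0.0519), which the first test, a median over 5 hosts (-0.05), had hidden, and for 11 whose hosts, among them GAS5 around 5 of them, were not analysed here. A lower recovery of the shorter RNAs in fructose met its prediction and may account for the pattern. Fold change rose with gene length across the 102 (Spearman's rho = 0.44, Pearson's r = 0.43). For rho the permutation p was 1e-04, the smallest 10000 permutations can give. Among the 102, the SNORD genes, with a median length of 75 bases, had a median of -0.38. The SNORA genes, at 135 bases, had -0.09. All 175 small nucleolar RNA genes, bright or dim, had a median of -0.10. Matched to these on brightness, probe sets without a gene name had -0.05 and protein-coding genes -0.0033. Handling of RNA and a biological change of SNORD genes both stay open.

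The runs of neighbouring genes that moved together may reflect gain or loss of chromosome segments in cells of one sugar, or regional control of transcription, which was not tested; the largest window, 0.27 against 0.13 in shuffled orders, describes the pattern and decides neither. A few strongly changed genes are argued against for 5 stretches on chromosomes 1, 4, 7 and X, which were found again from every other gene: of the genes between, 83.8% of 266 moved in the stretch's direction (95% exact binomial interval 78.9 to 88.1; a first version on dim genes, 55.6% of 1130, 52.6 to 58.5, was replaced because dim genes decide little). Both intervals treat neighbouring genes as independent, and neither measures the spread between cultures. Of the 266 genes, 113 were on chromosome X. The lowest share was 75% of 24 genes, in the chromosome 1 stretch from UFC1 to LAD1 (interval 53.3 to 90.2). A few strongly changed genes stay open for the other 4 stretches, 1 each on chromosomes 1, 2, 3 and 8, which left no genes for the test. There 69.4 to 84.9% of the genes moved in the stretch's direction, but they had been picked by their median. With the called genes kept in place and all others shuffled, the 95th percentile of the largest window on any chromosome was 0.18, above the largest absolute windows of these 4 (0.13, 0.15, 0.15 and 0.17). That largest window can come from the many called genes of chromosome X (53 higher, 2 lower) or chromosome 7 (22 and 1). It therefore does not test these 4 stretches on their own and decides nothing for them. All 9 stretches separated the 3 arrays of one sugar from the 3 of the other, which follows in part from their choice by that difference, so starting stocks that already differed and selection during adaptation cannot be told apart with these arrays.

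The higher cholesterol and estrogen receptor lists were set against brightness-dependent normalization. That is argued against by 10000 random lists matched on mean brightness, among which the smaller percentile of the list medians was 100. Of the other called lists, lysosome (99.68), NRF2 (99.9) and hexosamine (0.41) also lay near the ends. FOXO (97.34), MondoA and ChREBP (8.21) and mitosis (5.8) lay less far out, and brightness stays open for the medians of these. The chromosome stretches could contribute to the cholesterol list through NSDHL and EBP, but without the stretches the adjusted p was 1.20e-07 for cholesterol and 2.35e-07 for estrogen receptor targets, within ranges over all alternatives of 5.04e-10 to 0.110 and 1.62e-08 to 0.638. A response to the sugar stays among the open explanations as a hypothesis, and other differences between the separately kept cultures were not tested.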
